A study of Arabidopsis thaliana with 8 samples.

How the data were processed

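Small RNA from floral tissue of Arabidopsis thaliana was measured in 8 libraries, 2 biological replicates in each of 4 groups: Col-0 at 16 °C, Col-0 at 23 °C, Bur-0 at 23 °C and C24 at 23 °C. Per the labels' protocols, the small RNA fraction was taken from polyacrylamide gels, reverse transcribed with RevertAid enzyme (Fermentas) and amplified by PCR with Phusion polymerase. The deposited files list, per the file headers, each distinct read sequence of a library with its read count, and the values are whole counts with no normalization. The tools used for adapter trimming and any alignment are not given in the sources used here, and the files hold no coordinates. Sequences are 15 to 33 nt long, and the Bur-0 files end at 28 nt. Each library was kept as 1 replicate and no sample was left out.

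Reads of 18 to 30 nt without an undetermined base were used, 3445278 and 4946507 for Col-0 at 16 °C, 5864320 and 4403897 for Col-0 at 23 °C, 6281371 and 5492842 for Bur-0, and 5347918 and 6505453 for C24. Reads with an undetermined base made up 4.31% of Col-0 23 °C replicate 1. These sequences were matched exactly, on both strands, to the TAIR10.1 assembly, which is that of Col-0, and coordinates are 1-based on it. Counts were made for 3 tables. The miRNA table holds reads identical to 1 of 350 mature sequences, identical sequences of several loci being counted once under 1 name, so a change is relative to the miRNA pool. The gene table holds reads that match at 1 place only, over each of 36901 annotated genes, with rRNA, tRNA, snoRNA, snRNA and organelle genes left out. The window table holds 23 and 24 nt reads that match the nuclear genome at 1 place, in 500 bp windows by their 5' end. Strand was ignored, so the reads of overlapping or antisense genes cannot be told apart, and near-identical copies such as the PAI genes, PPR genes and miR159 and miR319 are uncertain. Tables held 216431 to 425320 miRNA reads, 622102 to 1412378 gene reads and 829371 to 1898590 window reads per library.

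Differences were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, quasi-likelihood) in R 4.3.3. All 8 libraries were fitted with 4 group means, since 2 libraries per group give few degrees of freedom alone. filterByExpr (minimum count 10, minimum total 15) kept 113 miRNAs, 6125 genes and 20528 windows. Libraries were scaled by TMM, with factors of 0.818 to 1.149 for miRNAs, 0.655 to 1.237 for genes and 0.768 to 1.28 for windows, and p-values were adjusted by Benjamini-Hochberg within a table and comparison at 0.05. "Rose" and "fell", or "higher" and "lower" beside a count, refer to features past that threshold. With library-size scaling in place of TMM, the median log2 change of all genes moved from -0.00 to -0.18 (Col-0 at 16 °C against 23 °C), from -0.13 to -0.55 (Bur-0 against Col-0), from -0.06 to -0.36 (C24 against Col-0) and from -0.01 to -0.13 (Bur-0 against C24). That of windows moved from -0.01 to -0.25, from -0.20 to -0.51 and from -0.22 to -0.49 in the first 3 comparisons, and that of miRNAs from -0.02 to 0.09 with temperature and from 0.12 to -0.16 in Bur-0 against Col-0. Changes are given relative to the TMM-scaled values.

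The share of 24-nt reads was compared by an exact two-sided permutation test. Lists fixed before the data were examined, 12 of miRNA families and 9 of genes, were tested with camera (limma 3.58.1, correlation 0.01 and an estimated correlation) and fry, each where at least 3 members were measured, with adjustment over the lists of a table and comparison. The miRNA lists take each measured mature sequence of a family, from either arm of its precursor. Their names describe the family, not each member. The natural-variation list was drawn from genes known to vary between strains. Where all libraries of a group had 0 reads, the fold is a lower bound against 3 counts over the group, and with 1 to 3 reads the ratio is given with its 95% exact counting interval.

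Features were named by a rule fixed before the data were examined. For each comparison, it took miRNAs past the threshold whose libraries of one group all lay above those of the other, up to the 6 largest rises and the 6 largest falls, and likewise up to 6 and 6 genes that have a symbol other than the locus identifier and a mean above 20 reads per library in at least 1 group. It also took every measured member of the TAS and natural-variation lists, the member of each miRNA list with the largest absolute log2 change, and the 2 largest rises and falls among windows. By chance, libraries of 2 against 2 do not overlap in 33.3% of cases. Other list members are named as examples of their list.

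Fixed alternatives were DESeq2 1.42.0, library-size scaling, no count filter, the replicate number as a block, a fit of only the groups compared, each library left out, reads shared between up to 50 places, 1 mismatch allowed, 1000 bp windows, miRNA reads within 2 nt of the mature ends, and, for the 24-nt share, distinct sequences, exactly matching reads or reads outside structural and organelle RNA. Reads up to 28 nt, crossed Bur-0 replicate numbers and list counts under each setting were added after the data were seen. The 1-mismatch search used bwa 0.7.19. On simulated counts for Bur-0 against Col-0, with log2 changes of 1, 2 and 3, edgeR recovered 22.2%, 62.5% and 92.3% of changed miRNAs (30 changed of 113), 11.6%, 63.9% and 81.4% of changed genes (200 of 6125) and 1.2%, 23.2% and 60.3% of changed windows (200 of 20528), and 8% of the gene calls and 1.9% of the window calls were false. Counting and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.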

Results

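Small RNA was sequenced from floral tissue of Arabidopsis thaliana in 8 libraries, which formed 4 groups of 2 biological replicates. The groups were the reference strain Col-0 grown at 16 °C, Col-0 grown at 23 °C, and the strains Bur-0 and C24, both grown at 23 °C, all in a 16 h light period. Libraries held 3823300 and 5443545 reads in Col-0 at 16 °C, 6314883 and 4676096 in Col-0 at 23 °C, 6515522 and 5640611 in Bur-0, and 5759453 and 6803249 in C24. The comparisons asked how Col-0 small RNAs differed at the lower growth temperature, and how the small RNAs of the strains differed from those of Col-0 and from each other. The labels give no preparation or sequencing batch, and any batch that followed the groups cannot be told apart from temperature or strain in all results below. Levels are TMM-scaled CPM (reads as a share of the miRNA, gene or window table of the library), given as mean ± SD with n = 2 libraries per group, and log2 changes are given ± SE. Intervals and lower bounds cover counting error only, because PCR reads without molecular identifiers are not independent molecules.

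The 24-nt class, the length of siRNAs that guide DNA methylation, was the most abundant length in each group. It made up 41.1% ± 2.85 of the 18 to 30 nt reads in Col-0 at 16 °C, 47.7% ± 6.17 in Col-0 at 23 °C, 58.8% ± 0.91 in Bur-0 and 51.3% ± 1.23 in C24 (SD, n = 2 each). The 21-nt class, which holds most miRNAs, made up 15.9% ± 4.27, 13.01% ± 1.08, 10.5% ± 0.38 and 11.9% ± 0.58 in the same order. The 24-nt share differed from that of Col-0 at 23 °C by -6.6 percentage points at 16 °C, 11.1 in Bur-0 and 3.67 in C24. None of these differences could pass 0.05, since the exact permutation test of 2 libraries against 2 reaches no lower than p = 0.333. The exact two-sided permutation test gave p = 0.333 for the temperature and the Bur-0 comparisons and p = 0.667 for C24. The C24 difference turned to -2.91 points among reads matching the reference exactly and to -0.7 points without Col-0 23 °C replicate 2, and the Bur-0 difference was 4.66 points among exactly matching reads.

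**Figure D1:**
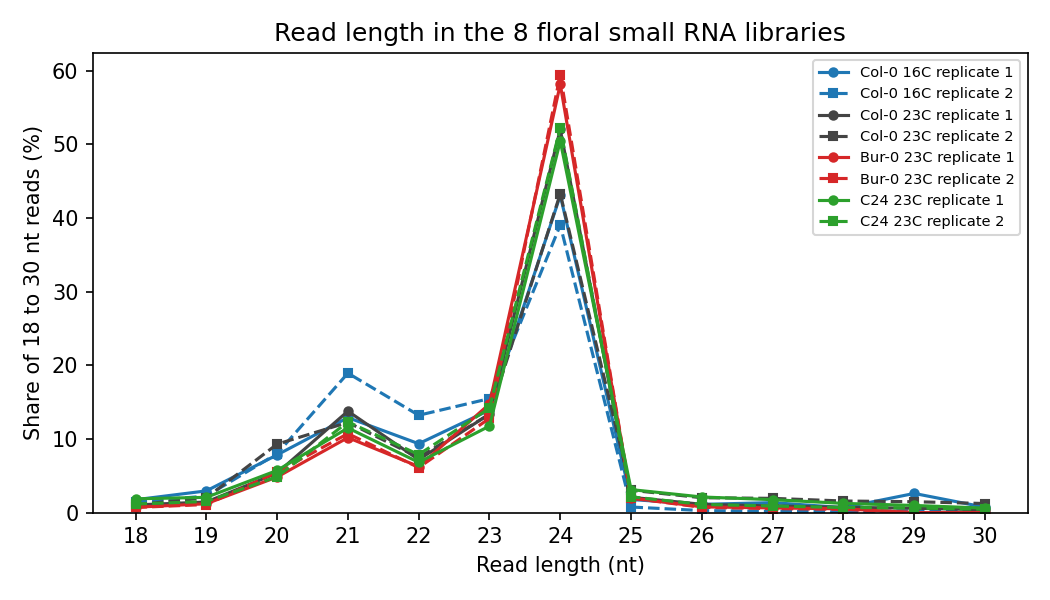
Percent of 18 to 30 nt reads (vertical axis) at each read length in nt (horizontal axis), with a line for each of the 8 libraries, solid with circles for replicate 1 and dashed with squares for replicate 2. The 24-nt peak lies between 39.0% and 59.4% in all 8 libraries.

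At 16 °C, Col-0 flowers held far more of several miRNAs than at 23 °C. miR824-5p, which targets the MADS-box gene AGL16, rose by 6.07 ± 0.59 on the log2 scale, from 551 ± 175 to 37131 ± 14107 CPM (adjusted p = 1.68e-06). miR172a, a regulator of AP2-like flowering genes, rose from 6946 ± 590 to 61505 ± 6548 (log2 3.15 ± 0.44, adjusted p = 0.000114), and miR390a-5p, which starts trans-acting siRNA production from TAS3 RNAs, rose from 9165 ± 3363 to 76982 ± 50438 (log2 3.07 ± 0.53, adjusted p = 0.000555). miR827 of the phosphate response rose 22.2-fold, miR472-5p 9.38-fold and miR161.2, which targets pentatricopeptide repeat (PPR) genes, 7.56-fold. miR394b-3p, with 52 reads against 0, was at least 19.4-fold higher, the floor being 3 counts over the group, as in all lower bounds here. miR779.2 and miR5663-5p rose by ratios of 23.5 (95% counting interval 6.12 to 201) and 18.5 (4.73 to 159.04) over few reads. miR771 fell from 427 ± 102 to 35.2 ± 12.7 (log2 -3.56 ± 0.71, adjusted p = 0.00203), and miR162a-5p (log2 -3.46) and miR869.2 (log2 -2.27) fell as well. The MYB-targeting miR159b-3p and miR159a and the TCP-targeting miR319a also passed as lower (log2 -4.19 ± 1.05, -2.92 ± 0.85 and -3.18 ± 0.82). Their reads are near-identical, and their high means at 23 °C rested on replicate 2, without which the log2 values were -0.75, -0.3 and -0.46 and none passed. The calls of miR771, miR162a-5p and miR779.2 were lost without Col-0 16 °C replicate 1 (adjusted p = 0.0551, 0.097 and 0.135), that of miR5663-5p without either 16 °C library or Col-0 23 °C replicate 2, and that of miR869.2 without either 16 °C library or Col-0 23 °C replicate 1 (log2 -0.68). Calls that held but shrank included miR162a-5p (log2 -2.13) without Col-0 23 °C replicate 2, and miR390a-5p (1.88), miR472-5p (2.24) and miR824-5p (5.33) without Col-0 16 °C replicate 2. The miR869.2 call was also lost with library-size scaling, without the low-count filter, with reads within 2 nt of the mature ends and with only the Col-0 libraries fitted (adjusted p = 0.0533, 0.183, 0.0563 and 0.115). The last of these ended the miR5663-5p call too. The miR159a call was lost with reads within 2 nt of the ends (0.0563).

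Of 113 miRNAs tested at 16 °C, 15 rose and 10 fell. Among 13 measured members of families reported to respond to ambient temperature, 1 rose (miR172a) and 2 fell (3 and 2 when adjusted over the list alone). The 12 phase change miRNAs gave 1 rise and 2 falls (3 and 3 adjusted over the list alone), the 30 flower and organ development miRNAs 4 rises and 4 falls (6 and 4), and the 56 members of conserved families 7 and 7 (10 and 8). Among 35 members of Brassicaceae-lineage families 6 rose, miR824-5p with the largest change, and 2 fell (7 and 2 adjusted over the list alone). The only measured phosphate miRNA, miR827, rose, as did 1 of 2 members of PPR-targeting families (miR161.2). So did 1 of 5 members of families that trigger trans-acting siRNAs (miR390a-5p). These counts were the same when adjusted over the list alone. Among 6 members of copper families, miR408-5p rose (log2 2.43 ± 0.82, adjusted p = 0.0413, and 0 adjusted over the list alone). Its call was lost without Col-0 23 °C replicate 2 and without either 16 °C library. Raw reads of miR408-3p, from the other arm of that precursor, went the other way, at 381 at 16 °C against 817 at 23 °C. Of 5 members of families that target the silencing machinery, miR162a-5p fell (1 rise and 2 falls adjusted over the list alone). The sulfate miRNA miR395a (log2 -0.98 ± 1.16) and the pollen-enriched miR845a (log2 -2.95 ± 1.12, adjusted p = 0.0635; 1 fall adjusted over the list alone) did not pass. No miRNA list moved against the other miRNAs (camera adjusted p = 0.922 for each of the 8 lists tested). The temperature-responsive families had a median log2 change of -0.15 and a mean of 0.42, and the conserved families -0.2 and 0.23, with camera pointing down for the latter and fry pointing up (fry adjusted p = 0.00254). Fry also passed the Brassicaceae-lineage (0.00311), temperature-responsive and flower and organ development lists (0.0499 each) as higher.

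**Figure D2:**
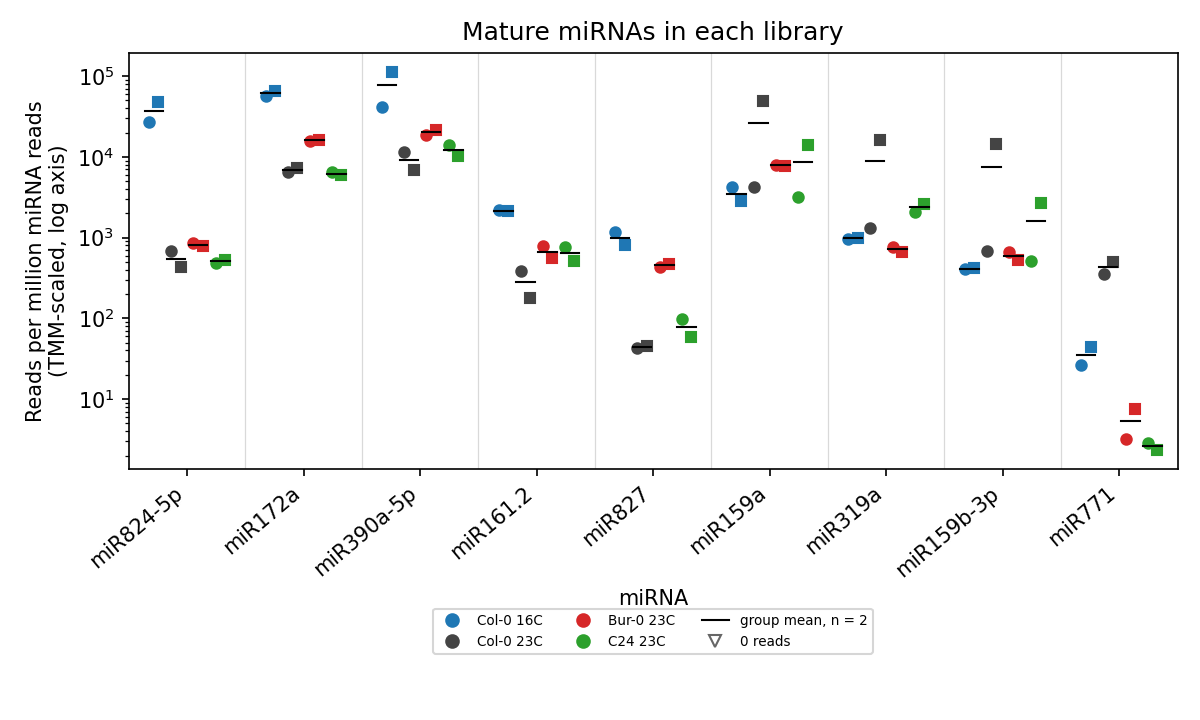
TMM-scaled CPM over miRNA reads (vertical log axis) of 9 miRNAs in the 4 groups, with circles for replicate 1, squares for replicate 2 and bars for the mean of 2 libraries. miR824-5p averages 37131 in Col-0 at 16 °C and 551 at 23 °C, and the 23 °C libraries of miR159 and miR319 lie far apart.

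Small RNAs from several genes that form secondary siRNAs were also more abundant at 16 °C. Of 7 measured trans-acting siRNA (TAS) genes, 3 rose and 4 did not pass (5 rose when adjusted over the list alone): TAS2 (log2 1.21 ± 0.30, 11025 ± 1243 against 4754 ± 1044, adjusted p = 0.0322), TAS3b (log2 1.79 ± 0.32, adjusted p = 0.00731) and TASIR-ARF (log2 1.71 ± 0.39, adjusted p = 0.0221). TAS1A, TAS1B, TAS1C and TAS3 had log2 values of 1.14, 1.18, 0.86 and 0.68. The TAS2 call was lost without the low-count filter (log2 1.04, adjusted p = 0.422), with library-size scaling (adjusted p = 0.087), without Col-0 16 °C replicate 2 (adjusted p = 0.0865) and without Col-0 23 °C replicate 2 (log2 0.87, adjusted p = 0.149), and that of TASIR-ARF without Col-0 16 °C replicate 2 (adjusted p = 0.123; log2 1.05 and past without Col-0 23 °C replicate 2). Of 16 PPR genes, which encode organelle RNA-binding proteins, 6 rose and 10 did not pass (12 rose when adjusted over the list alone). The largest was AT1G62910 (chromosome 1, 23298948 to 23301141), where reads went from 67.1 ± 4.15 to 831 ± 45.6 CPM (log2 3.63 ± 0.28, adjusted p = 4.16e-05) and 99.4% were 20 to 22 nt long. AT1G62914 (log2 2.21 ± 0.32) and AT1G12775 (log2 1.71 ± 0.32) rose too, although PPR copies are similar enough that reads with a variant can match a relative. Both lists stood above the other genes in camera (adjusted p = 2.45e-05 for TAS and 4.38e-09 for PPR), which was lost with an estimated correlation (adjusted p = 0.414 and 0.27 with an estimated correlation). In fry the PPR list passed (adjusted p = 0.00747) and the TAS list did not (0.0717). The auxin receptor AFB3, the only riser among 4 such genes (1 adjusted over the list alone), had a log2 change of 1.17 ± 0.29 (adjusted p = 0.0302). AP2, a floral organ identity gene and a target of miR172, rose with a log2 change of 1.295 ± 0.35 (adjusted p = 0.0446), as 1 of 2 measured genes of its list (1 adjusted over the list alone). The AP2 call was lost with DESeq2 (adjusted p = 0.135), the replicate block (0.06) and without Col-0 23 °C replicate 2 (0.142). Those of AP2 and AFB3 were lost with library-size scaling (0.0796 and 0.068), without the low-count filter, with only the Col-0 libraries fitted and without Col-0 16 °C replicate 2 (0.296 and 0.157). That of AT1G12775 was lost with only the Col-0 libraries fitted and without Col-0 16 °C replicate 2 (0.0697 and 0.0855). That of AT1G62914 was lost when reads matching several places were shared among them (0.0812). No member passed among 3 silencing machinery genes, 3 RNA-directed DNA methylation reporters, 5 green tissue genes and 7 natural-variation genes, whether adjusted over all genes or adjusted over the list alone, and edgeR gave an unadjusted p under 0.05 for 1 silencing machinery gene and DESeq2 called 0 of these genes. All these values are of small RNA reads over the genes, and mRNA was not measured. Of 10 flowering and ambient temperature genes, 0 had enough reads to be measured.

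**Figure D3:**
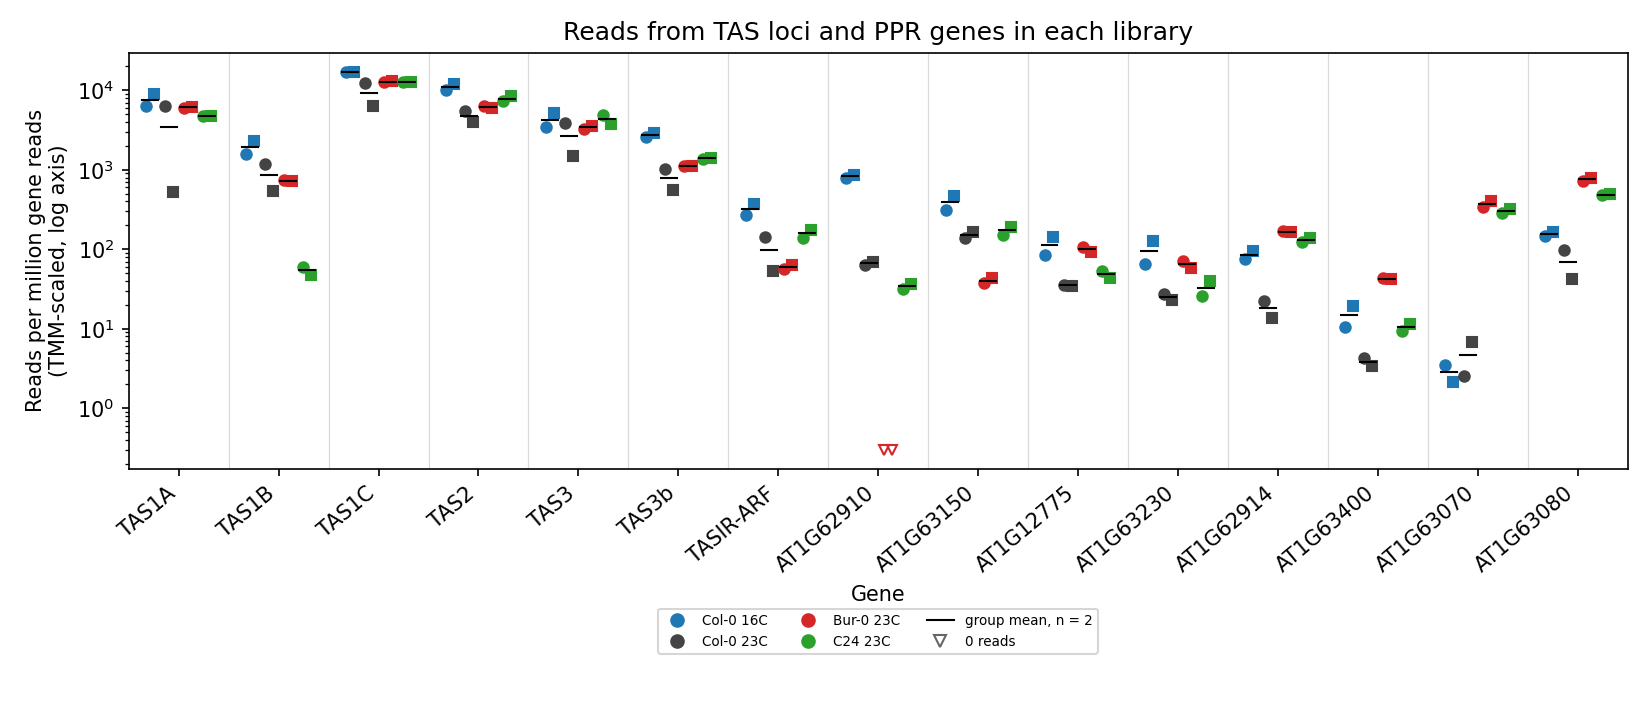
TMM-scaled CPM over gene reads (vertical log axis) from TAS and PPR genes, with circles for replicate 1, squares for replicate 2, bars for the mean of 2 libraries and open triangles for 0 reads. AT1G62910 averages 831 in Col-0 at 16 °C, 67.1 at 23 °C and 0 in Bur-0.

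Across 6125 genes, 240 rose and 223 fell at 16 °C, or 201 and 340 with library-size scaling. Calls covered 18.6% of miRNA genes and 7.4% of protein-coding genes, a difference that was not tested. Among named genes, MIR824 (log2 6.24 ± 0.46), MIR779 (5.69 ± 0.77), MIR827 (4.85 ± 0.39) and MIR833b (4.26 ± 0.47) had the largest rises beside LURE1.1 (chromosome 5, 17370473 to 17370857), which encodes a pollen tube attractant peptide and rose from 11.1 ± 10.9 to 266 ± 29.5 with 87.7% of its reads 23 to 24 nt long. PORB, a chlorophyll synthesis gene, rose by 4.17 ± 0.51 with 94% of reads 20 to 22 nt long, but it overlaps AT4G27450, as MIR824 overlaps AT4G24413 and MIR833b AT1G78476, and reads of such pairs cannot be told apart. PP2-B8 fell from 446 ± 262 to 61.4 ± 21.7 (log2 -2.83 ± 0.41). MIR5023 fell by a ratio of 55.5 (9.66 to 2220.3), XBAT34 by 10.95 (3.52 to 55.1) and MEE66 by 2.72 on the log2 scale. MIR169e was at least 7.06-fold lower, and MIR159b fell by 3.55 on the log2 scale, though only by 0.69 without Col-0 23 °C replicate 2. Of 20528 windows of 500 bp with 23 to 24 nt reads, 664 rose and 596 fell (52.7% of calls higher, or 26.9% with library-size scaling). The window at chromosome 3, 16436001 to 16436500, outside annotated genes, rose from 11.7 ± 7.04 to 909 ± 168.03, and that at chromosome 2, 4131001 to 4131500, in the pseudogene AT2G10600, was at least 9.68-fold higher. Windows at chromosome 3, 12702001 to 12702500, and chromosome 4, 3864001 to 3864500 (pseudogene AT4G06660), were at least 8.95-fold and 5.97-fold lower. Without either 16 °C library, the calls of MIR169e, MIR159b, XBAT34, MEE66 and these windows were lost, except that of the window at 16436001. Smaller but still past were MIR779 (log2 4.36) and MIR5023 (-4.84) without Col-0 16 °C replicate 1, and LURE1.1 (3.66), MIR833b (3.63) and PP2-B8 (-2.17) without Col-0 23 °C replicate 2. Without the latter library XBAT34 also shrank, from -3.42 to -2.39. The MIR159b call was also lost with DESeq2 (adjusted p = 0.0679), the replicate block (0.0628), shared reads (0.0804) and only the Col-0 libraries fitted (0.126). That of MEE66 was lost with the replicate block (0.0528) and only the Col-0 libraries (0.0865), and that of XBAT34 with the latter (0.123). With shared reads MIR169e (0.136) and the 2 lower windows (0.0565 and 0.0734) did not pass.

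These calls came from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Fitting the 4 Col-0 libraries alone left 17 miRNAs, 81 genes, 109 windows, 0 TAS genes (4 in DESeq2 on all libraries) and 2 PPR genes, and leaving out 1 library moved the counts to between 11 and 51 miRNAs, 141 and 1212 genes, 73 and 6462 windows, 1 and 7 TAS genes, and 2 and 10 PPR genes. Col-0 23 °C replicate 2 stood apart, with 9.39% of its reads from tRNA against 1.69% in replicate 1 and 0.27% from TAS genes against 0.612%, and without it 18 miRNAs, 654 genes, 2866 windows, 2 TAS and 5 PPR genes passed.

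Bur-0 flowers differed from Col-0 flowers at the same temperature at many loci, some of which had no read matching the reference in 1 of the strains. GLR2.3 (chromosome 2, 10516780 to 10520684), a glutamate receptor-like channel gene, gave 1252 ± 85.4 CPM in Col-0 and 0 in Bur-0, at least 722-fold lower. HR1 (chromosome 3, 18722234 to 18723310), a relative of the RPW8 resistance genes, gave 570 ± 58.2 in Bur-0 and 0 in Col-0, at least 385-fold higher (adjusted p = 3.62e-07). The tryptophan synthesis genes PAI1, PAI2 and PAI3, which are near-identical copies, were at least 119-fold, 78.9-fold and 133-fold higher in Bur-0, and 53.3%, 71.8% and 8.2% of their reads were 20 to 22 nt long.

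Genes chosen because they are known to vary between strains moved mostly upward in Bur-0. Of 7 measured, 6 rose and 1 fell, with the same counts adjusted over the list alone. PAI1, PAI2 and PAI3 had 0 reads in Col-0 at 23 °C and were measured through the strains, so they could only be called higher. As near-identical copies they also are not separate evidence, and both points enter the list tests. Besides the PAI genes, IIL1 of leucine synthesis rose from 6.72 ± 1.38 to 95.2 ± 33.1 (log2 3.77 ± 0.47, adjusted p = 3.07e-05), the folate transporter gene FOLT1 by 2.78 ± 0.48 and QQS of starch metabolism by 2.68 ± 0.50 (2.06 without Col-0 23 °C replicate 2), while HISN6B of histidine synthesis was at least 5.12-fold lower. The list passed in camera (adjusted p = 0.0028) but not with an estimated correlation (adjusted p = 0.153 with an estimated correlation), and it passed in fry (2.14e-05), as did the PPR list (0.00923). Of 16 PPR genes, 10 rose and 2 fell (10 and 2 adjusted over the list alone). AT1G63070 went from 4.73 ± 3.05 to 376 ± 45.6 (log2 6.35 ± 0.41), AT1G63080 rose by 3.42 and AT1G62914 by 3.17, whereas AT1G62910, the PPR gene with the largest rise at 16 °C, was at least 38.7-fold lower by reads that match at 1 place and AT1G63150 fell by 1.90 (camera adjusted p = 0.0104, and 0.748 with an estimated correlation). Of 4 auxin receptor genes, GRH1 (log2 3.97 ± 0.68) and AFB2 (log2 1.19 ± 0.35) rose (3 adjusted over the list alone), and of 5 green tissue genes the small RNA reads of RBCS1A and RCA fell by 1.45 and 1.48 (2 adjusted over the list alone). When reads matching several places were shared among them, AT1G62910 turned to 0.38 and AT1G63150 to -0.34 and neither passed. The AFB2 call was lost with library-size scaling (adjusted p = 0.104) and without Bur-0 replicate 1 (0.0647). Those of RBCS1A and RCA were lost without Bur-0 replicate 1 (0.157 and 0.0992) and without Col-0 23 °C replicate 2 (log2 -0.81 and -0.71). RCA also did not pass without Bur-0 replicate 2 (0.0797) and with shared reads (0.062). No TAS gene of 7 passed in edgeR (0 adjusted over the list alone, 0 at an unadjusted p under 0.05 and 0 in DESeq2), and TAS2, for example, had a log2 change of 0.37 ± 0.30. The TAS result depended on the control libraries. Without Col-0 23 °C replicate 1, TAS1A (log2 3.56), TAS1C (1.06), TAS3 (1.25) and TAS3b (1.04) passed as higher in Bur-0, and without replicate 2, TASIR-ARF (-1.28) and TAS1B (-0.72) passed as lower, as TASIR-ARF did with library-size scaling (-1.15).

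**Figure D4:**
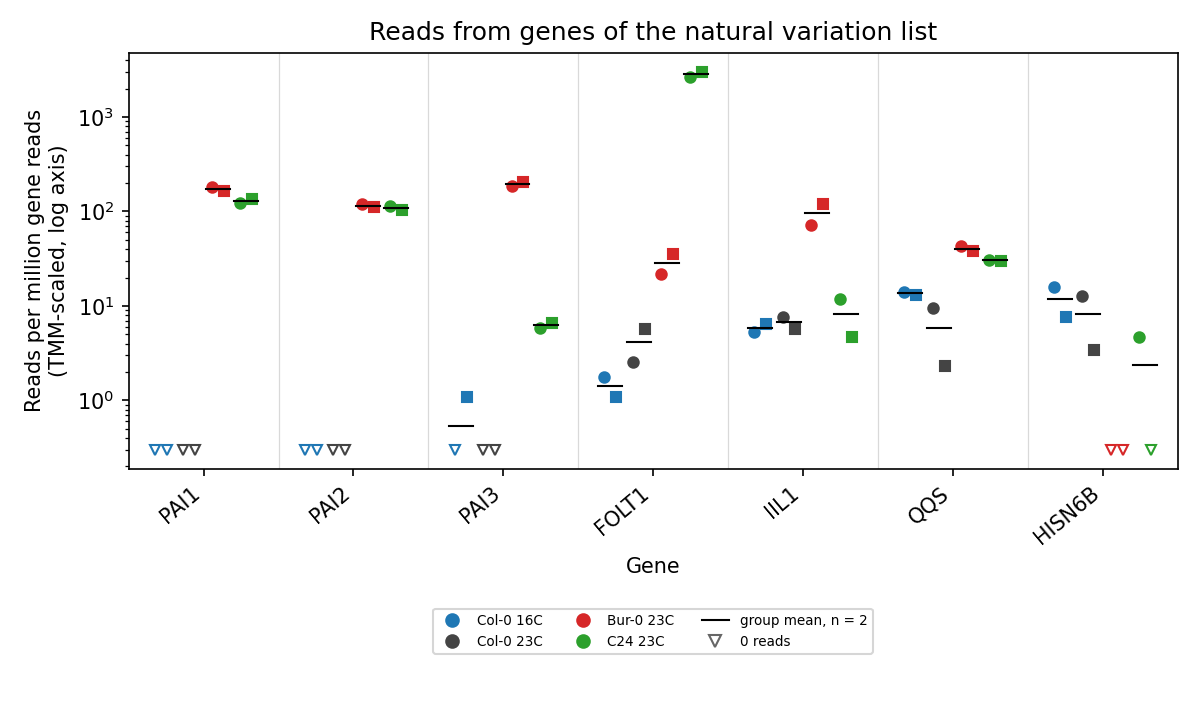
TMM-scaled CPM over gene reads (vertical log axis) from 7 genes known to vary between strains, with circles for replicate 1, squares for replicate 2, bars for the mean of 2 libraries and open triangles for 0 reads. FOLT1 averages 2819 in C24 and 28.4 in Bur-0, and PAI1 and PAI2 have 0 reads in each Col-0 library.

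Among 113 miRNAs, 13 were higher and 17 lower in Bur-0 than in Col-0. miR398a-5p, from a precursor of the copper-responsive family, rose from 12.9 ± 5.57 to 342 ± 34.4 (log2 4.62 ± 0.96, adjusted p = 0.00458), miR827 by 3.35 ± 0.64, and miR157a-3p, miR846-3p, miR843 and miR5647 by 3.85, 3.34, 2.92 and 2.84 on the log2 scale. No read of miR5659, miR3933, miR8183, miR4243 or miR867 was found in Bur-0, which made them at least 25.3-fold, 18.3-fold, 15.5-fold, 14.3-fold and 7.01-fold lower. miR771 was lower by a ratio of 78.6 (26.6 to 384). For miR771, 184 Bur-0 reads carried a sequence 1 base away from the Col-0 form. Members of temperature-responsive families rose in 3 of 13 cases (3 rises and 2 falls adjusted over the list alone), phase change miRNAs in 3 of 12 (3 and 1), and conserved families showed 8 rises and 6 falls among 56 (8 and 6). Of 6 copper miRNAs 1 rose and 1 fell, but 1 rose and 5 fell when adjusted over the list alone. No miRNA list passed in camera, whose smallest adjusted p was 0.323. Fry, which tests a list without the other miRNAs, passed the conserved (adjusted p = 0.00121), temperature-responsive (0.0307), phase change, flower and organ development, and Brassicaceae-lineage lists (0.0477 each) as higher. The calls of miR867, miR843 and miR5647 were lost without either Bur-0 library. That of miR5647 was also lost with DESeq2 (adjusted p = 0.0842), library-size scaling (0.0725), no low-count filter (0.0578), the replicate block (0.0564) and only these groups fitted (0.0592), and the last also ended those of miR157a-3p, miR846-3p and miR843. The miR4243 call was lost without Bur-0 replicate 1 and that of miR157a-3p without Bur-0 replicate 2. Without Col-0 23 °C replicate 2 the log2 changes of miR157a-3p and miR843 were smaller, at 3.11 and 2.26.

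Of 6125 genes, 1386 had more and 1750 fewer reads in Bur-0 than in Col-0, and of 20528 windows 4059 had more and 6744 fewer. Of the genes with fewer reads, 420 (24%) had 0 reads in Bur-0. Other named genes with 0 matching reads in Bur-0 included the endoglucanase genes GH9B11 and GH9B12 (at least 297-fold and 179-fold lower), the pseudogene CYP79A4P (301-fold), NF-YC6 (246-fold) and MPC (192-fold). Named genes with 0 reads in Col-0 included SCRL10 (at least 158.49-fold higher), CAD6 (99.9-fold) and BGLU21 (82.0-fold). The largest window rise lay at chromosome 2, 8621501 to 8622000, over GC1 and AT2G19960, with 7345 reads against 1, a ratio of 8057 (1446 to 318280), and a window at chromosome 2, 9323001 to 9323500, outside annotated genes, was at least 524-fold higher. Windows at chromosome 3, 15633501 to 15634000 (pseudogene AT3G43730), and at chromosome 5, 14046501 to 14047000, were at least 2115-fold and 1822-fold lower. Library-size scaling gave 985 genes higher and 2216 lower, 3024 windows higher and 7440 lower, and 6 miRNAs higher and 24 lower. DESeq2 gave 1071 genes higher and 1449 lower, and 2467 windows higher and 5798 lower. The miRNA count was 10 when only the Bur-0 and Col-0 23 °C libraries were fitted, 12 and 13 without Bur-0 replicates 1 and 2, and 55 without Col-0 23 °C replicate 1. The HISN6B call was lost without Col-0 23 °C replicate 1 and without either Bur-0 library.

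C24 flowers also differed from Col-0 flowers at many loci. FOLT1 (chromosome 5, 26513262 to 26515800) gave 2819 ± 257 CPM in C24 and 4.15 ± 2.24 in Col-0 (log2 9.43 ± 0.45, adjusted p = 1.55e-07), and 83.7% of its C24 reads were 20 to 22 nt long. PAI1 and PAI2 were at least 88.8-fold and 73.9-fold higher, PAI3 at least 4.28-fold, and QQS rose by 2.27 ± 0.50 (1.57 without Col-0 23 °C replicate 2). In contrast, TAS1B fell from 856.27 ± 453 to 54.2 ± 8.5 CPM (log2 -3.99 ± 0.41, adjusted p = 6.1e-06), while TAS3b rose by 0.82 ± 0.31 (adjusted p = 0.0467). TAS1B (chromosome 1, 18549204 to 18550042) overlaps AT1G07613. The TAS3b call was lost with DESeq2, with library-size scaling, with 1 mismatch allowed, without the low-count filter, with only these groups fitted, without either C24 library and without Col-0 23 °C replicate 2 (log2 0.33, adjusted p = 0.461). The TAS1B fall was smaller, -3.32 without Col-0 23 °C replicate 1, -2.13 when 1 mismatch was allowed and -2.88 when reads matching several places were shared among them.

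Of the 7 genes known to vary between strains, 5 rose in C24 and 2 did not pass (5 adjusted over the list alone), with log2 values of 0.22 for IIL1 and -1.93 for HISN6B. The near-identical PAI genes, with 0 reads in Col-0 at 23 °C, could only be called higher here too. The list passed in camera (adjusted p = 0.00223) but not with an estimated correlation (adjusted p = 0.172 with an estimated correlation). In fry it passed (6.15e-05), as did the PPR (0.00755) and methylation reporter lists (0.0198). Of 16 PPR genes 8 rose and 1 fell (10 and 1 adjusted over the list alone), AT1G63070 by 6.05 ± 0.41, AT1G62914 by 2.83 and AT1G63080 by 2.78, with AT1G62910 at -0.96 (camera adjusted p = 0.00223, and 0.559 with an estimated correlation). The PPR count of rises was 5 with DESeq2, with library-size scaling, with only these groups fitted and without either C24 library. Of 7 TAS genes 1 rose and 1 fell (0 and 1 adjusted over the list alone), with a median log2 of 0.69 and a mean of -0.02. AFB2 and AFB3 rose by 1.04 and 0.85 (2 of 4 auxin receptor genes adjusted over the list alone), and DML1, a DNA demethylase gene also called ROS1, rose by 1.38 ± 0.39 as 1 of 3 methylation reporters (1 adjusted over the list alone). None of these 3 calls was made by DESeq2 (adjusted p = 0.0749, 0.0642 and 0.084). All 3 were also lost with library-size scaling, without the low-count filter and without either C24 library. AFB2 and AFB3 did not pass with 1 mismatch allowed, nor AFB3 with only these groups fitted and without Col-0 23 °C replicate 1 (log2 0.56). The AT1G62910 call was lost without the low-count filter (adjusted p = 0.139), without C24 replicates 1 (0.119) and 2 (0.072), and with shared reads (log2 0.34).

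Among 113 miRNAs 6 were higher and 9 lower in C24. miR846-5p and miR842, whose families target jacalin lectin genes, were at least 18.4-fold and 9.33-fold higher, and miR846-3p rose by 3.87 ± 0.80. miR166c, a regulator of HD-ZIP leaf and flower polarity genes, rose from 46741 ± 27603 to 156524 ± 19963 (log2 1.74 ± 0.47, adjusted p = 0.0146), and miR165b of the same targets rose by 1.68 ± 0.50. No read of miR3440b-3p, miR5659, miR825, miR8183 or miR4243 was found in C24, which made them at least 89.9-fold, 33.6-fold, 21.5-fold, 20.7-fold and 19.0-fold lower. The pollen-enriched miR845a fell by a ratio of 38.9 (6.5 to 1583) and miR771 by 156.75 (43.0 to 1301). Sequences 1 base from the Col-0 form were read in C24 for miR771 (215 reads), miR825 (117), miR3440b-3p (74) and miR8183 (52). No member passed among 13 temperature-responsive, 12 phase change and 5 silencing-machinery miRNAs, also when adjusted over the list alone, with 1, 0 and 1 at an unadjusted p under 0.05 in edgeR and 0 calls in DESeq2, and the conserved families gave 2 rises among 56 (0 adjusted over the list alone). No miRNA list passed in camera (smallest adjusted p = 0.683) or in fry (smallest 0.465).

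Of 6125 genes, 1042 had more and 1773 fewer reads in C24 than in Col-0, and of 20528 windows 3735 had more and 7018 fewer. Library-size scaling gave 772 genes higher and 1984 lower, and 2704 windows higher and 7565 lower. DESeq2 gave 734 genes higher and 1597 lower, and 2173 windows higher and 6264 lower. Pseudogenes, which include annotated transposon remnants, were lower in 964 of 2784 cases (34.6%) and higher in 414 (14.9%). The acid phosphatase gene PAP24 was at least 145-fold higher, LBD32 at least 71.0-fold, and BGLU35 by a ratio of 571 (195 to 2771). MPC, the homeodomain gene HDG9, MIR5659 and RALFL30 had 0 reads in C24 and were at least 210-fold, 186-fold, 96.9-fold and 79.7-fold lower, and the retroposon SADHU9-1 was lower by a ratio of 1003 (180 to 39669) and CYP79A4P by 987 (177 to 39004). The log2 change of BGLU35 shrank from 8.99 to 7.85 without Col-0 23 °C replicate 1. Those of SADHU9-1 and CYP79A4P shrank from -9.66 to -9.02 and from -9.58 to -8.94 without C24 replicate 1. Windows at chromosome 2, 7580501 to 7581000, and 11196501 to 11197000, the latter over the G protein gene GP ALPHA 1, were at least 1410-fold and 636-fold higher, and windows at chromosome 3, 15632501 to 15633000, and chromosome 4, 8799001 to 8799500, at least 554-fold and 494-fold lower. The miRNA count fell to 1 when only the C24 and Col-0 23 °C libraries were fitted, was 9 without either C24 library and 39 without Col-0 23 °C replicate 1, and the calls of miR166c and miR165b were lost without Col-0 23 °C replicate 2 (adjusted p = 0.122 for both) and without either C24 library, as was that of miR845a. Those of miR166c and miR165b were lost with reads within 2 nt of the mature ends as well (0.0793 for both).

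Bur-0 and C24 differed from each other about as widely. PSEUDOSRKA (chromosome 4, 11383433 to 11387188), a remnant of the receptor kinase gene of self-incompatibility, gave 1572 ± 11.4 CPM in C24, 75.5% of them 20 to 22 nt long, and 0 in Bur-0, at least 912-fold lower, though the antisense or overlapping AT4G21366 shares its reads. FOLT1 was lower in Bur-0 by 6.65 ± 0.38 on the log2 scale (log2 -6.65, adjusted p = 1.52e-07), whereas PAI3 was higher by 4.93 ± 0.38, IIL1 by 3.55 ± 0.46 and TAS1B by 3.75 ± 0.41. MIR169j, MIR774a and the cellulose synthase-like genes CSLB01 and CSLB02 gave mostly 23 to 24 nt reads in Bur-0, and they were higher there by at least 250-fold, a ratio of 802 (274 to 3892), at least 229-fold and at least 60.9-fold. NF-YC6, KCR2, LBD32, MIR3933 and the myrosinase gene TGG2 had 0 reads in Bur-0 and were at least 331-fold, 94.8-fold, 60.6-fold, 46.9-fold and 42.7-fold lower.

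In all, 1531 of 6125 genes were higher and 1265 lower in Bur-0 than in C24. The natural-variation list gave 2 higher and 1 lower of 7 (2 and 1 adjusted over the list alone), the TAS list 1 and 1 (1 and 1), and the PPR list 6 and 3 of 16 (6 and 3, camera adjusted p = 0.957), with AT1G62910 at least 20.1-fold lower in Bur-0 (log2 0.04 and not past when reads matching several places were shared). Medians and means of these lists differed in sign, at 0.41 and -0.18 for natural variation, -0.33 and 0.24 for TAS and 0.33 and -0.28 for PPR. Of 5 green tissue genes, RBCS1A, CAB1 and RCA were lower in small RNA reads (log2 -1.46, -2.57 and -1.64, with 4 adjusted over the list alone). All 3 calls were lost without Bur-0 replicate 1 (adjusted p = 0.217, 0.0785 and 0.0896) and without C24 replicate 1 (log2 -0.77, -1.02 and -0.9), that of RCA without Bur-0 replicate 2 (0.0626) and that of RBCS1A without the low-count filter (0.0617). Of 113 miRNAs, 15 were higher and 8 lower in Bur-0, or 9 and 12 with library-size scaling. miR825 was at least 27.9-fold, miR5020b 10.6-fold, miR3440b-3p 8.86-fold and miR1888a 6.65-fold higher, miR5641 rose by 3.86 ± 1.12 and miR845a was higher by a ratio of 25.3 (4.01 to 1049). For miR825 and miR3440b-3p this holds for the Col-0 form alone, since C24 gave 117 and 74 reads of a form 1 base away, against 63 and 20 reads of the Col-0 form in Bur-0. miR3933, miR846-5p and miR5655 were at least 20.6-fold, 16.8-fold and 6.02-fold lower, and miR391-5p was lower at 943 ± 13.8 against 6771 ± 122 (log2 -2.84 ± 0.57, adjusted p = 0.00398), with miR8175 and miR5642a at -3.90 and -2.40. Temperature-responsive families gave 3 higher of 13 (4 adjusted over the list alone), led by miR398a-5p (log2 3.17 ± 0.85), and conserved families 6 higher and 2 lower of 56 (6 and 2), with no list passing in camera (smallest adjusted p = 0.638). In fry the conserved (adjusted p = 0.00095), temperature-responsive (0.0112) and phase change lists (0.045) passed as higher, and no gene list did (smallest 0.0636). The miRNA count depended on the libraries, with 41 when only the Bur-0 and C24 libraries were fitted and 5, 3, 7 and 3 when Bur-0 replicate 1, Bur-0 replicate 2, C24 replicate 1 or C24 replicate 2 was left out. Of the miRNAs named for this comparison, miR3933 and the Col-0 form of miR825 passed with each library left out and the others lost their call without at least 1. The miR845a call was also lost with DESeq2 (adjusted p = 0.0883), that of miR846-5p with reads within 2 nt of the mature ends (log2 -1.25) and that of miR5642a without the low-count filter (0.0527).

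Reads from Bur-0 and C24 matched the Col-0 reference less often than Col-0 reads. Of 24-nt reads, 71.6% ± 9.83 matched exactly in Col-0 at 16 °C, 79.1% ± 8.72 at 23 °C, 37.6% ± 2.72 in Bur-0 and 52.3% ± 0.7 in C24 (SD, n = 2 each). Among sequences read at least 10 times in their library, the shares were 94.6%, 96.8%, 65.5% and 65.4%. Counts in the strains cover only loci where the strain and the reference are identical over the read, by the exact matching used.

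**Figure D5:**
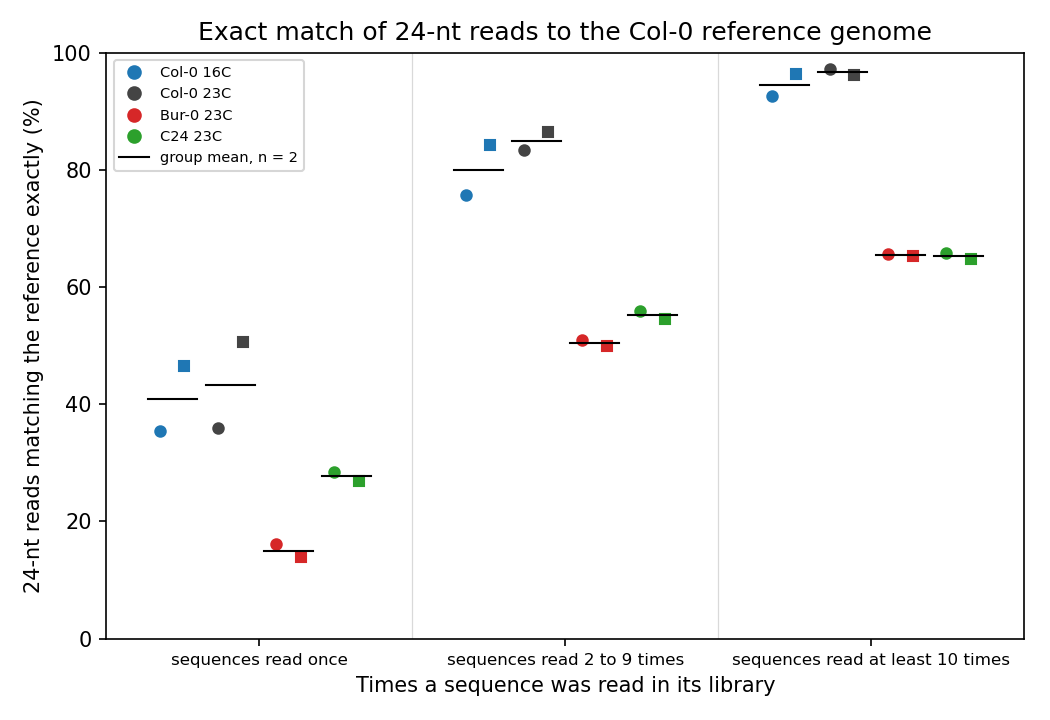
Percent of 24-nt reads that match the reference exactly (vertical axis) by how often their sequence was read in the library (horizontal axis), with circles for replicate 1, squares for replicate 2 and bars for the mean of 2 libraries. Sequences read at least 10 times match in 65.5% of Bur-0 and 65.4% of C24 reads, against 96.8% in Col-0 at 23 °C.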

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

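In this part, the tests of growth at 16 °C, of reads 1 base from the reference and of read errors were chosen after the result was seen.

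Reads shorter than 18 nt, which enter no comparison, held 1 sequence of 17 nt that averaged 55785 CPM of all reads in the Col-0 libraries grown at 16 °C (57490.1 and 54079.8). The same sequence had 126.7 and 2002.7 CPM in Col-0 at 23 °C, 100.7 and 88.6 in Bur-0, and 312.9 and 71.4 in C24. It matches chromosome 2 at 14894941 to 14894957, where 16 of its 17 bases lie at the 5' end of the snoRNA gene AtU61.

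The libraries hold size-selected small RNA, so their reads do not measure the level of the whole snoRNA. More RNA from the whole snoRNA gene therefore stays open as a cause. Short reads from the rest of the gene had 1.52 times the CPM in the highest 16 °C library as in the highest Col-0 23 °C library. Those reads were few, 29 against 25 over the groups, a ratio of 1.38 (95% counting interval 0.78 to 2.45) that lies below the change of the sequence itself. Growth at 16 °C remains possible, the lower 16 °C library holding 27.0 times the level of the highest 23 °C library, but the design confounds it with any library batch or size marker used for that group, so these cannot be told apart. Of the 18 to 24 nt reads that contain the sequence in Col-0 at 16 °C, 49.4% matched the genome exactly, a share that leaves open whether the sequence comes from that place at all.

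Many abundant 24-nt sequences of the strains were never read in Col-0, and part of these had no match to its genome within 1 mismatch. The search allowed no gaps, so a sequence without such a match can still have a related place in that genome. In Bur-0, 7674 of the 23119 sequences read at least 10 times in each library were never read in Col-0, and 3335 of these had no match within 1 mismatch. In C24, 9888 of 28451 were never read in Col-0, and 4482 had no such match. In the other direction, 2813 of 14747 sequences read at least 10 times in each Col-0 library at 23 °C were never read in the strains, and 97.5% of them matched the genome exactly. These sets of sequences carried 7.65% of 24-nt reads in Bur-0, 11.95% in C24 and 4.49% in Col-0 at 23 °C. The Col-0 set had to be absent from both strains and each strain set from Col-0 alone, so its share is not directly comparable.

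The lower match of strain reads and the lower read counts of many genes were weighed against reading errors and small variants. Read errors were argued against as the whole cause of the gap between Bur-0 and Col-0, because it stayed at 31.35 percentage points among 24-nt sequences read at least 10 times. They may explain the gap between Bur-0 and C24, which was 0.08 points among those sequences, while sequences read once matched exactly in 15.03% of Bur-0 and 27.7% of C24 reads. Reads exactly 1 base from the reference were argued against as the main cause of these calls. Of the genes with fewer reads, 90.3% in Bur-0 and 92.4% in C24 stayed lower when 1 mismatch was allowed. For the lower genes with 0 exact reads, 420 in Bur-0 and 436 in C24, the median level with 1 mismatch allowed was 0.0% of that in Col-0. The size of the fall was not weighed for the other lower genes, and it can be smaller where the call stays. Reads with more than 1 single-base difference are not reached by this search. They, larger sequence differences, lost loci and loss of siRNA production in the strains stay open and were not tested.

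Against Col-0, 327 genes moved in opposite directions in Bur-0 and C24, 210 of them higher in Bur-0 and 117 higher in C24, where independent lists would give 401.2 and 297.7. All 327 also passed in edgeR's test of Bur-0 against C24, which their choice by opposite calls nearly fixes. KCR2 fell in Bur-0 and rose in C24 (log2 -8.55 and 1.64, Bur-0 against C24 -10.19, adjusted p = 1.32e-06), as did MIR5023 (-3.34 and 1.94, difference -5.28, adjusted p = 2.25e-06) and PSEUDOSRKA (-7.36 and 6.10, difference -13.46, adjusted p = 1.47e-07). XBAT34 rose in Bur-0 and fell in C24 (3.19 and -1.53, difference 4.72, adjusted p = 1.16e-05). KCR2 and PSEUDOSRKA had 0 reads in Bur-0, so their fitted values are no bounds, and both overlap other genes. No explanation was tested for these genes.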

How the results depend on the processing

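In this part, the list counts under each setting, the limit of reads to 28 nt and the crossed Bur-0 numbers were chosen after the data were seen, and the other alternatives were fixed before.

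Of the features named by rule, 0 calls turned in direction, but AT1G62910, named as an example of its list, went from lower in both strains to 0.38 in Bur-0 and 0.34 in C24 with shared reads. For the 24-nt share, 2 values turned. The share in C24 against Col-0 at 23 °C, 3.67 percentage points, became -2.91 among exactly matching reads and -0.7 without Col-0 23 °C replicate 2, with -0.7 to 8.03 over the libraries left out. The Bur-0 difference of 11.14 became 4.66 among exactly matching reads and ranged from 6.77 to 15.5 over the libraries left out, and the temperature difference of -6.6 ranged from -10.97 to -2.24. The lower match of strain reads to the reference enters the exact-match values by construction. The other causes were not tested.

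A fit of only the groups compared has 2 residual degrees of freedom in place of 4, and it gave fewer calls with temperature, at 81 genes against 463 and 109 windows against 1260. It also called 10 miRNAs against 30 in Bur-0 and 1 against 15 in C24, both compared with Col-0, but 41 against 23 in Bur-0 compared with C24. Sharing reads between several places raised the temperature counts to 769 genes and 2437 windows, and dropping the count filter raised the miRNA count in C24 to 25. Why these moved was not tested beyond the construction of each fit.

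Leaving out 1 library assumes that the lone library of its group varies like the others. The temperature counts then ranged from 11 to 51 miRNAs, 141 to 1212 genes and 73 to 6462 windows, each highest without Col-0 23 °C replicate 1. The miRNA counts ranged from 12 to 55 in Bur-0 against Col-0, 9 to 39 in C24 against Col-0 and 3 to 7 in Bur-0 against C24. Without Col-0 23 °C replicate 2 the temperature comparison gave 18 miRNAs, 654 genes and 2866 windows. In C24 against Col-0 the call of miR165b was lost without either C24 library and without Col-0 23 °C replicate 2 (adjusted p between 0.065 and 0.369).

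Counts of changed genes and windows in the strains stayed within 1.5 times under all alternatives, at 2269 to 3905 genes in Bur-0 and 2203 to 3418 in C24 against Col-0, 2099 to 3515 in Bur-0 against C24, and 7903 to 14487 and 7764 to 13867 windows in Bur-0 and C24. The limit of 1.5 times holds for totals and not for each direction. With DESeq2 the windows higher than in Col-0 went from 4059 to 2467 in Bur-0 and from 3735 to 2173 in C24. DESeq2 called 354, 2520, 2331 and 2253 genes and 30, 31, 14 and 23 miRNAs in the 4 comparisons. The count of TAS genes that rose at 16 °C was 3, with 0 in the fit of only the groups compared and 1 to 7 over the libraries left out, and that of PPR genes was 6, with 2 and 2 to 10. The natural-variation list kept counts of 6 in Bur-0 and 5 in C24 in every setting.

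The replicate numbers were checked for pairing. Same-numbered deviations correlated at -0.004 to -0.137 over miRNAs in the comparisons except C24 against Col-0 (0.316), at -0.075 to -0.011 over genes and at -0.03 to 0.063 over windows. Little sign of pairing was thus seen outside the miRNAs of C24 against Col-0, where a shared replicate effect stays open. With the replicate block, the counts were 29, 33, 16 and 29 miRNAs, 438, 3013, 2694 and 2696 genes, and 1852, 10672 and 10607 windows. The 24-nt share differences stayed at -6.6, 11.14 and 3.67 by construction, because the mean of paired differences equals the difference of group means. With the Bur-0 numbers crossed, 36 miRNAs passed against Col-0 and 32 against C24.

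Among named features, the calls of miR824-5p, miR172a, miR390a-5p, miR161.2 and miR827 at 16 °C held in all alternatives, as did GLR2.3, HR1, FOLT1 and PSEUDOSRKA in the strains. Over all alternatives, 25 values of named genes and 26 of named miRNAs at 16 °C no longer passed, while 271 and 147 were the same. In simulated counts for Bur-0 against Col-0, a log2 change of 1 was recovered for 22.2% of miRNAs, 11.6% of genes and 1.2% of windows. Only 200 of 6125 genes and 200 of 20528 windows were changed there, whereas 51.2% and 52.6% were called in the data. Recovery depends on the share changed, so the gene and window values do not show how often small changes were missed here. For miRNAs the shares were closer, at 30 of 113 changed and 26.5% called.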

Other observations

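In this part, the weighing of the covariance by its jackknife SE and of Col-0 23 °C replicate 2 by the log2 changes kept without it was chosen after the results were seen, and the other tests were fixed before.

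Among 24-nt reads that match the reference exactly, the 5' base, which guides loading into Argonaute proteins, was A more often than any other base. Such reads were 37.6% of 24-nt reads in Bur-0 and 52.3% in C24, so the strain values leave out the rest. The share of A among the matching reads was 58.5% and 57.0% in Col-0 at 16 °C, 54.9% and 45.4% in Col-0 at 23 °C, 58.7% and 61.5% in Bur-0, and 52.4% and 52.3% in C24. Reads from miRNA genes made up 11.4% ± 4.02 of 18 to 30 nt reads in Col-0 at 16 °C, 9.73% ± 0.924 at 23 °C, 6.79% ± 0.105 in Bur-0 and 8.95% ± 0.17 in C24 (SD, n = 2 each), and those from TAS genes 0.8% ± 0.166, 0.441% ± 0.242, 0.454% ± 0.026 and 0.507% ± 0.014. These shares count exactly matching reads over all reads, and 77.7% of reads matched in Col-0 at 23 °C, 41.5% in Bur-0 and 58.9% in C24. The lower match lowers the strain shares by construction, so they do not show a smaller miRNA or TAS fraction in the strains.

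Changed windows with 23 to 24 nt reads lay both outside and over annotated genes, and the 2 classes were not tested against each other. At 16 °C, 3.9% of 9925 windows outside genes and 2.6% of 10603 over genes were higher, and 3% and 2.8% were lower. In Bur-0 against Col-0, 33.7% of 9925 windows outside genes and 32% of 10603 over genes were lower, and 18.2% and 21.2% were higher. In C24 the shares were 33.5% and 34.8% lower, and 19.2% and 17.2% higher. Lower windows often had 0 reads in the strain, 2672 of 6744 in Bur-0 (39.6%) and 2946 of 7018 in C24 (42%). Higher windows had 0 reads in Col-0 at 23 °C less often, 671 of 4059 in Bur-0 (16.5%) and 569 of 3735 in C24 (15.2%). Only reads identical to the Col-0 reference were counted, so 0 reads in a strain do not by themselves show a loss of siRNAs.

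Several miRNAs changed alike at 16 °C and in Bur-0 when each was set against Col-0 at 23 °C. Of the miRNAs past the threshold in both, 5 rose and 4 fell in both, where independent lists would share 1.7 and 1.5, and 0 moved in opposite directions. Simulated unchanged groups, set against simulated controls, shared 0.1 calls of the same sign on average and at most 1, but such groups hold no effects, which raise the number of calls. All 8 libraries were drawn anew in each simulation, so the values of the actual control libraries were not held fixed. miR827 had log2 changes of 4.47 and 3.35 and miR172a 3.15 and 1.21. miR771 had -3.56 and -6.25, but 184 Bur-0 reads carried a form of miR771 1 base away, which exact matching leaves out. The covariance of the fold changes was 1.728 with a jackknife SE of 0.5, against a mean of 0.717 and a highest value of 1.235 in 100 simulations of unchanged groups against simulated controls. Without Col-0 23 °C replicate 1 it was 4.323 and without replicate 2 it was 1.227. A lone control was not simulated, so these 2 values count for neither side. With all libraries the covariance lay above the highest simulated value by 0.493, less than its SE, so the shared controls stay open as a cause. Part of the excess may come from them, as they are 2 libraries and cannot be split. The covariance between differences that share no library, -1.344 with an SE of 0.705, says nothing on this, because changes shared by Bur-0 and C24 enter it with a negative sign. Col-0 23 °C replicate 2 was argued against as the sole cause of the set. Without it 100% of the 9 kept their sign, and 6 of them, miR827, miR172a, miR771, miR158a-3p, miR158b and miR393b-3p, kept at least 82.0% of both log2 changes (median over the 9 of the lower share 91.7%), although 3 stayed past the threshold in both comparisons. It stays open for the other 3, since the log2 changes of miR159b-3p became -0.75 and -0.21, those of miR319a -0.46 and -0.9 and those of miR162a-5p -2.13 and -0.72.

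Bur-0 and C24 also shared calls against Col-0. In the gene table, 478 genes rose and 1016 fell in both, where independent lists would share 235.8 and 506.6, and part of the excess over independent lists may come from the shared controls. The covariance was 5.029 (jackknife SE 0.208), against a mean of 0.221 and a highest value of 0.234 in 20 simulations of unchanged groups that share simulated controls. Missing matches to the Col-0 reference enter both comparisons as well. With 1 library left out, the counts of changed genes ranged from 2269 to 3434 in Bur-0 and from 2203 to 3008 in C24.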
